A study of Homo sapiens with 6 samples.

How the data were processed

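RNA sequencing was done on H1 (WA01) human embryonic stem cell-derived trophoblast 24 h after transfection with VTCN1 siRNA or scrambled siRNA, with 3 libraries per group made with a stranded mRNA kit, per the labels' protocols. Per the submitters' processing notes the tools were cutadapt, Bowtie, TopHat, TopHat2 2.0.13, Cuffdiff 2.2.1 and HTSeq (written there as version 011.1) with the genome build GRCh38; their roles, settings and the annotation are not given in the sources used here. The authors deposited 1 table of log2 values, with gene symbols in rows. No source states the log base, the transform or the normalization. The base was inferred from the values, which run from -2.16 to 21.21 and give plausible read totals only as powers of 2. Low genes lie close to a common value per gene in all libraries, as in a moderated log transform, so fold changes of low genes may be understated. A row listed at exactly 0 in every library was treated as carrying no value.

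Of 10 columns, 6 were used. The header gives the siRNA, the time, the H1 passage, the flow cell and the lane of each column but no replicate number of the sample titles, so columns were mapped to groups and not to single samples. Passages 53 and 54 have a second lane per library, and these 4 columns were not used. Beside 58522 gene rows, 5 rows were counters that name no gene and were left out; after conversion from the log2 scale, ambiguous, unassigned and multiply aligned reads made up 19.9% to 20.6% of a column. The file gives no counts, so depth and counting error per gene are unknown. The 10 highest genes made up 5.50% to 5.76% of a column.

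The planned test was for counts, with a fallback for other units. Because the values were already log2, they were tested directly by limma 3.58.1 with a mean-variance trend in R 4.3.3, with group as the only term and all 6 libraries, and with no pseudocount. Genes with a mean value of 5 or more were tested, a limit set after the unit was seen. P-values were adjusted over 13488 genes by the Benjamini-Hochberg method at 0.05. The 24 gene lists, with 635 entries, were fixed before the data were examined; lists with at least 2 tested members were tested by limma's camera with a preset correlation of 0.01 and adjusted over the lists. Estimated correlations and the fry test were alternatives. Camera compares a list with the other genes, and fry tests whether its members move one way on balance, or in its mixed form whether they change in either direction. Tables were made with Python 3.11.15 and pandas 2.3.3. Coordinates are from GENCODE release 29 on GRCh38, matched by symbol for 37697 of 58522 gene rows. Intervals of shares are 95% exact binomial intervals.

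Genes named are VTCN1; HLA-A, HLA-B, HLA-C and B2M; the 10 largest log2 fold changes in each direction among called genes whose groups did not overlap, without pseudogenes and genes without a symbol; and up to 4 called members of each list with the smallest p, or up to 2 that did not pass where none was called. The planned limit of a mean CPM of 1 was replaced by the filter on the log2 value. Other genes are named only in the closing section or as list members at 0, and were chosen after their values were seen.

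The fit was tested on simulated data for this comparison, with 13488 genes, the observed means and residual spreads and 200 changed genes. It recovered 61 of 67 genes changed by 0.5 on the log2 scale (91.0%), 66 of 67 changed by 1 and 66 of 66 changed by 2, and 15 of 208 calls were false (7.21%). Residuals were drawn independently, without the correlation within passages described next, so this share need not hold for the deposited values. Directions drawn at random in each passage, with sizes kept, gave 447 to 617 calls without the passage block and 5 to 26 with it. Genes were drawn independently there too, so these ranges may be too narrow.

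The passages pair the libraries by the header. Their deviations from the group means were negatively correlated across genes within each passage, with Pearson's r of -0.80, -0.71 and -0.62 in passages 52, 53 and 54; genes are not independent replicates. The passage means of a gene varied little, with a median SD of 0.018, against a median of 0.052 for the mean size of the passage differences divided by 2. The unblocked fit was the planned main fit and was kept. With a negative correlation within pairs its standard errors are too small for most genes: they were larger with passage as a block for 99.0% of the tested genes, with a median of 0.0707 against 0.0472. For some named genes, such as CUTA and IFIT3, they were smaller with the block. P-values of both fits rest on the spread of the deposited values over passages of a single cell line. If values were adjusted within passages before deposit, which the sources used here do not record, p-values and SDs would not measure the original spread between passages. Alternatives fixed before the data were examined were median-of-ratios, upper-quartile and equal-total centring of columns, no filter, leaving out each library, an adjusted p under 0.01 and a log2 size of at least 1. The passage block, passages 53 and 54 alone, quantile normalization, a filter at 8, a robust variance prior, a fit without trend and mixed fry were chosen after seeing the data.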

Results

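Gene expression was measured by RNA sequencing in trophoblast cells made from the human embryonic stem cell line H1 (WA01). The cells were differentiated with BMP4, the activin/Nodal receptor inhibitor A83-01 and the FGF receptor inhibitor PD173074, a treatment known as BAP. On day 3 of BAP they were transfected with 10 nM of an siRNA duplex against VTCN1 or of a scrambled control duplex, and RNA was collected 24 h later, on day 4. VTCN1, also called B7-H4, is a cell surface protein of the B7 family that restrains T cells. The study asked which pathways VTCN1 regulates in these cells, and its title names differentiation, proinflammatory responses and MHC class I expression. There were 3 control and 3 knockdown libraries, and the table's header ties them to passages 52, 53 and 54 of the H1 cells, with a library of each group per passage. The passage 52 pair was sequenced on another flow cell than the other 2 pairs. Collections at 48 h and 72 h that the design mentions were not analysed here. The deposited values are on a log2 scale without read counts, so the depth of each library is unknown. Summed over genes after conversion from the log2 scale, they came to between 23036444 and 24414816 per library. Per the series' design text the knockdown sample titled replicate 1 lacks raw data, and the columns do not show which of them it is. Of 58522 gene rows, 22292 were listed at 0 in every library, and 13488 genes with a mean value of 5 or more were tested. Differences between log2 values are called log2 fold changes below and may be drawn toward 0 by the authors' transform, which is not given in the sources used here. Unless stated otherwise, SEs below are from the fit without the passage block and are too small for most genes.

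VTCN1 was lower in the knockdown library of every passage. Its value was 13.19 ± 0.03 (SD, n = 3) in control and 11.16 ± 0.13 (SD, n = 3) in knockdown libraries, a log2 fold change of -2.03 ± 0.06 (SE), or 4.09-fold lower, with an adjusted p of 1.40e-05 by limma and of 1.30e-05 with passage as a block. The SD of the knockdown libraries was larger than that of the control libraries, and the groups did not overlap. Within passages the difference was -1.90 in passage 52, -2.04 in passage 53 and -2.15 in passage 54. The gene lies on chromosome 1 at 117143587 to 117210960 on the minus strand of GRCh38 and is annotated as protein-coding. Among all genes tested, 627 were higher and 610 lower in knockdown than in control libraries at an adjusted p under 0.05, and 2709 had an unadjusted p under 0.05. Most of these differences were small, with a median absolute log2 fold change of 0.25. Among the 37 called genes with an absolute log2 fold change of at least 1, 33 were higher and 4 were lower. All 37 moved the same way in all 3 passages, but so did all 1237 called genes, since a call favours genes that do. With passage as a block, 214 genes were higher and 142 lower, all of them among the genes called without it. Each gene's direction was also drawn at random in each passage, with its sizes kept. In 20 such draws 447 to 617 genes were called without the block, with a median of 541.5, and 5 to 26 with it. Genes were drawn independently, so the correlation between genes was lost and these ranges may be too narrow. Exchanging the labels of the passage 52 pair alone gave 1363 called genes without the block and 14 with it. In passages 53 and 54 alone, 1549 genes were higher and 1073 lower, of which 582 and 436 were called in all 3 passages together. That fit, here and below, had no passage block, so its p-values may be too small and its counts too high.

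Genes induced by type I interferon, the antiviral cytokine family, formed most of the large increases. Of 54 tested genes on the type I interferon list, 42 rose, none fell and 12 did not pass, and 44 rose when adjusted over the list alone. The block left 40, and 43 when adjusted over the list alone. The median log2 fold change of the list was 1.03 (camera, adjusted p = 2.49e-58; adjusted p = 0.494 with an estimated correlation). IFIT3, an inhibitor of viral replication on chromosome 10 at 89327894 to 89340971, rose by 2.60 ± 0.10 (SE) on the log2 scale, or 6.07-fold, from 7.92 ± 0.11 to 10.53 ± 0.21 (SD, n = 3 each, adjusted p = 1.89e-05). MX1, an antiviral GTPase on chromosome 21 at 41420304 to 41459214, rose by 2.33 ± 0.12 (adjusted p = 3.60e-05) and IFIT1 by 2.29 ± 0.10 (adjusted p = 2.09e-05). The ubiquitin-like modifier ISG15 rose by 2.13 ± 0.11 (adjusted p = 3.71e-05). OAS3, OAS2 and OAS1, synthases of the second messenger that activates RNase L, rose by 2.23, 2.06 and 1.63 on the log2 scale. IFI6, PARP14 and the double-stranded RNA sensor IFIH1 rose by 1.78, 1.77 and 1.77. These were the 10 largest increases without overlap between the groups, and IFITM1, BST2 and CMPK2, among the list members with the smallest p, had log2 fold changes of 1.63, 1.43 and 1.43. List members were not alike across passages, with a median difference of 0.84 in passage 52, 1.37 in passage 53 and 1.32 in passage 54. Of 46 members that were higher by at least 0.5 in both passages 53 and 54, 37 were higher and 9 lower in the knockdown library of passage 52.

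On the interferon gamma list, 14 of 30 genes were below the filter. Of the 16 tested, 5 rose and 11 did not pass, and 5 also rose when adjusted over the list alone. The block left 2, and 5 when adjusted over the list alone. In passages 53 and 54 alone 11 rose. The list's median difference was 0.05 in passage 52, 0.34 in passage 53 and 0.30 in passage 54. The list's median was 0.19 (camera, adjusted p = 2.21e-06; adjusted p = 0.494 with an estimated correlation). APOL6 rose by 1.63 ± 0.09 (SE) on the log2 scale and SOCS1, a feedback inhibitor of JAK signalling, by 0.49 ± 0.06. On the list of interferon genes, receptors and nucleic acid sensors, 14 of 26 members were tested. All interferon genes on it were below the filter, so only receptors, sensors and signalling genes were tested. Among these 14, 2 rose and 2 fell, and 3 rose and 2 fell when adjusted over the list alone. The list's adjusted p by camera was 0.250, and 0.555 with an estimated correlation. Without a filter, with 26 tested, it was 0.0168 by camera with the preset correlation. The nuclear DNA sensor IFI16 rose by 1.17 ± 0.08 and the antiviral zinc finger protein ZC3HAV1 by 0.56 ± 0.13, whereas the interferon receptor subunit IFNAR2 and the DNA sensor AIM2 fell by 0.14 ± 0.03 and 0.10 ± 0.02. With passage as a block IFI16 alone of these 4 passed, with an adjusted p of 3.30e-04, and the ZC3HAV1 difference was 0.04 in passage 52 against 0.84 in passage 53.

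**Figure D1:**
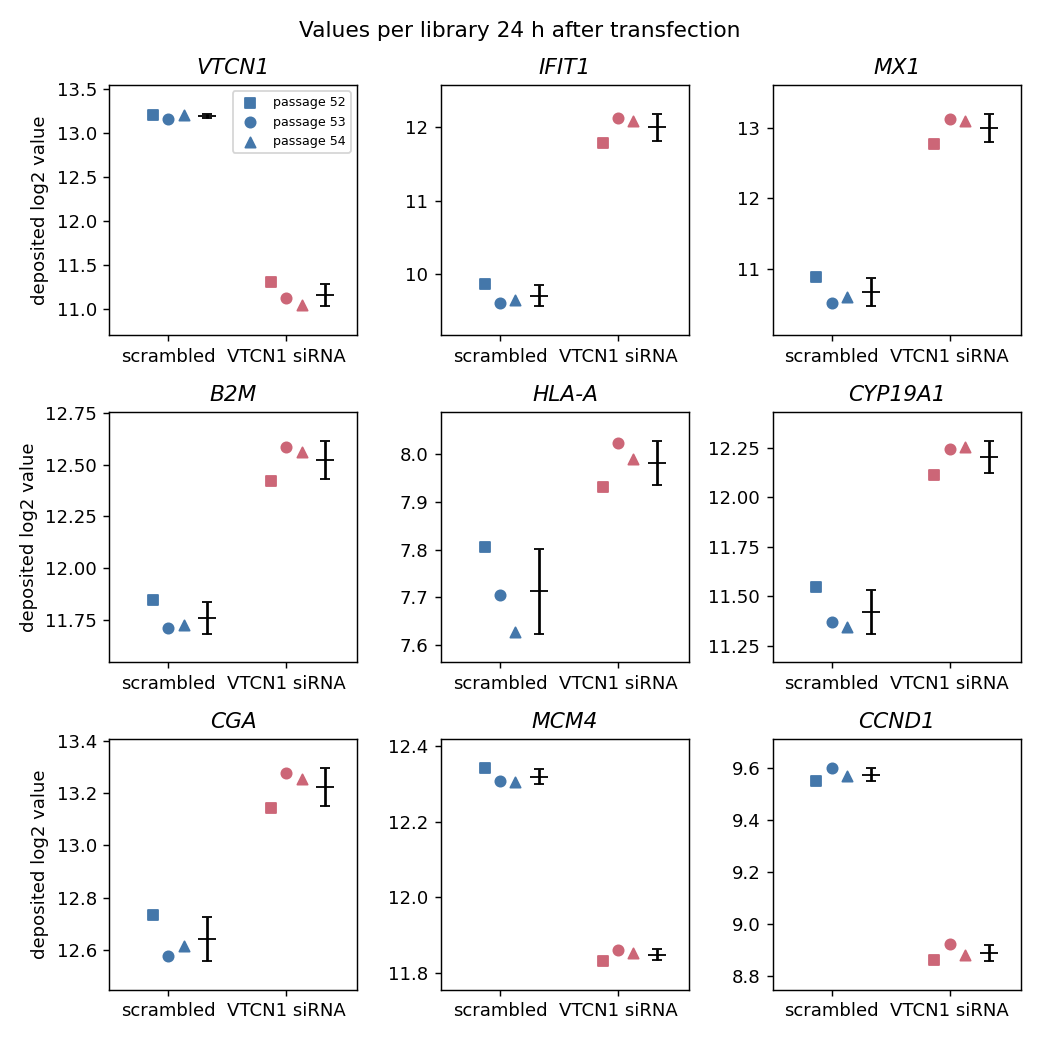
Deposited log2 values of 9 genes in the 3 control (blue) and 3 knockdown (red) libraries, with a marker shape for each passage and black bars for the mean and SD of each group. The axes do not start at 0; in each panel the 3 knockdown values lie apart from the 3 control values, with VTCN1 means of 13.19 and 11.16 and CYP19A1 means of 11.42 and 12.20.

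Among genes of MHC class I antigen presentation, B2M, ERAP1, PSME2 and HLA-A rose. Of 22 genes on this list, 12 were tested: 4 rose, none fell and 8 did not pass, and 7 rose when adjusted over the list alone (camera, adjusted p = 4.91e-06; adjusted p = 0.494 with an estimated correlation). With passage as a block 2 rose, and 7 when adjusted over the list alone. In passages 53 and 54 alone 10 rose. The list's median difference was 0.05 in passage 52, 0.35 in passage 53 and 0.32 in passage 54. B2M, the light chain of all class I molecules, lies on chromosome 15 at 44711487 to 44718877. It rose from 11.76 ± 0.08 to 12.52 ± 0.09 (SD, n = 3 each), a log2 fold change of 0.76 ± 0.06 (SE), or 1.70-fold, with an adjusted p of 2.49e-04 and of 0.00257 with passage as a block. ERAP1, which trims peptides for class I, rose by 0.41 ± 0.05 (adjusted p = 0.00144) and the proteasome activator subunit PSME2 by 0.32 ± 0.07 (adjusted p = 0.0357, and 0.151 with passage as a block). HLA-A, on chromosome 6 at 29941260 to 29945884, rose by 0.27 ± 0.05 from 7.71 ± 0.09 to 7.98 ± 0.05 (adjusted p = 0.0176, and 0.0976 with passage as a block). Like HLA-B and HLA-C it lies within the MHC region described below, where most genes were listed at 0, so its value and difference are uncertain. HLA-C had values of 5.71 ± 0.14 and 5.73 ± 0.13, a log2 fold change of 0.02 ± 0.08 that did not pass (adjusted p = 0.940). HLA-B was below the filter, with mean values of 3.15 in control and 3.13 in knockdown libraries. TAP1, TAP2, PSMB8 and PSMB9 were listed at 0 in all 6 libraries. In the MHC region of chromosome 6, between 28503296 and 33457548, 114 of 173 protein-coding genes were listed at 0, which is 65.9% (95% exact interval 58.3 to 72.9). On the rest of chromosome 6 the share was 5.95% of 824 genes. The 2 tested genes of the MHC class II list, CIITA and CD74, had log2 fold changes of 0.06 and 0.09 and did not pass.

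On the list of NF-kB targets and inflammatory cytokines, 2 of 18 tested genes rose and 16 did not pass, and 4 rose when adjusted over the list alone (camera, adjusted p = 0.0214; adjusted p = 0.494 with an estimated correlation). TNFAIP2 and TNFAIP3, the latter a feedback inhibitor of NF-kB, rose by 0.34 ± 0.06 (SE) and 0.27 ± 0.05 on the log2 scale. Neither passed with passage as a block, and the list's adjusted p was 0.0573 in passages 53 and 54 alone. Of 37 genes on the list, 18 were below the filter and 1 was listed at 0. Among 14 tested immune checkpoint molecules, 2 rose and 12 did not pass, with 2 when adjusted over the list alone (camera, adjusted p = 0.0409; adjusted p = 0.494 with an estimated correlation). CD274, also called PD-L1, rose by 0.32 ± 0.05 and the butyrophilin BTN3A2 by 0.21 ± 0.04, and neither passed with passage as a block (adjusted p = 0.0539 and 0.0998). The checkpoint list's adjusted p was 0.100 in passages 53 and 54 alone and 0.137 with a filter at 8, which left 7 tested members.

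Tested genes of the syncytiotrophoblast, the hormone-producing multinucleated layer of the placenta, were mostly higher in knockdown libraries. The list has 46 genes, of which 19 were below the filter and 3 were listed at 0. These included all listed genes for the chorionic gonadotropin beta subunit, placental lactogen and pregnancy-specific glycoproteins. Of 24 tested members, 14 rose, 1 fell and 9 did not pass, with the same numbers when adjusted over the list alone, and 13 rose and none fell with passage as a block. The list's median log2 fold change was 0.36 (camera, adjusted p = 2.04e-13; adjusted p = 0.494 with an estimated correlation). CYP19A1, the aromatase that makes estrogens, rose from 11.42 ± 0.11 to 12.20 ± 0.08 (SD, n = 3 each), a log2 fold change of 0.78 ± 0.07 (SE, adjusted p = 3.53e-04). CGA, the alpha subunit of chorionic gonadotropin, rose by 0.58 ± 0.06 (adjusted p = 7.66e-04). The endogenous retroviral envelope gene ERVV-2 rose by 0.61 ± 0.06 and LGALS16, a galectin, by 0.50 ± 0.04.

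Other trophoblast and amnion lists did not pass by camera in the main fit. Of 21 tested extravillous trophoblast genes, 4 rose and 17 did not pass, and 4 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.0833). In passages 53 and 54 alone 9 rose and none fell, and the list passed toward higher values (adjusted p = 0.00380), as it did without the control or the knockdown library of passage 52 (0.0213 and 0.0164). Over all 3 passages its adjusted p was 0.703 with an estimated correlation and 0.764 with the block as well. The list's median difference was -0.11 in passage 52, 0.09 in passage 53 and 0.19 in passage 54. HTRA4, SNAI1, CCR1 and ITGA5 rose by 0.28, 0.25, 0.19 and 0.33 on the log2 scale, and with passage as a block HTRA4 and CCR1 passed. Of 38 tested genes of cytotrophoblast and trophoblast progenitors, 3 rose, 2 fell and 33 did not pass, also when adjusted over the list alone (camera, adjusted p = 0.381). In passages 53 and 54 alone 13 of them rose and 5 fell. Their median difference was -0.04 in passage 52, 0.18 in passage 53 and 0.06 in passage 54. The transcription factor genes TFAP2C, DLX3 and MSX2 rose by 0.49 ± 0.06, 0.42 ± 0.05 and 0.31 ± 0.05 (SE). TP63, a marker of proliferative cytotrophoblast, fell by 0.23 ± 0.03, and with passage as a block TFAP2C and DLX3 passed. Of 25 tested amnion genes, 1 rose and 4 fell, and 2 rose and 4 fell when adjusted over the list alone (camera, adjusted p = 0.234; 0.0251 and 0.0445 without the control or knockdown library of passage 54; 0.753 with an estimated correlation). ANKRD1 fell by 0.62 ± 0.04, CLDN10 by 0.34 ± 0.04 and SEMA3C by 0.32 ± 0.04, whereas the cadherin CDH10 rose by 0.34 ± 0.05, and all 4 passed with passage as a block.

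**Figure D2:**
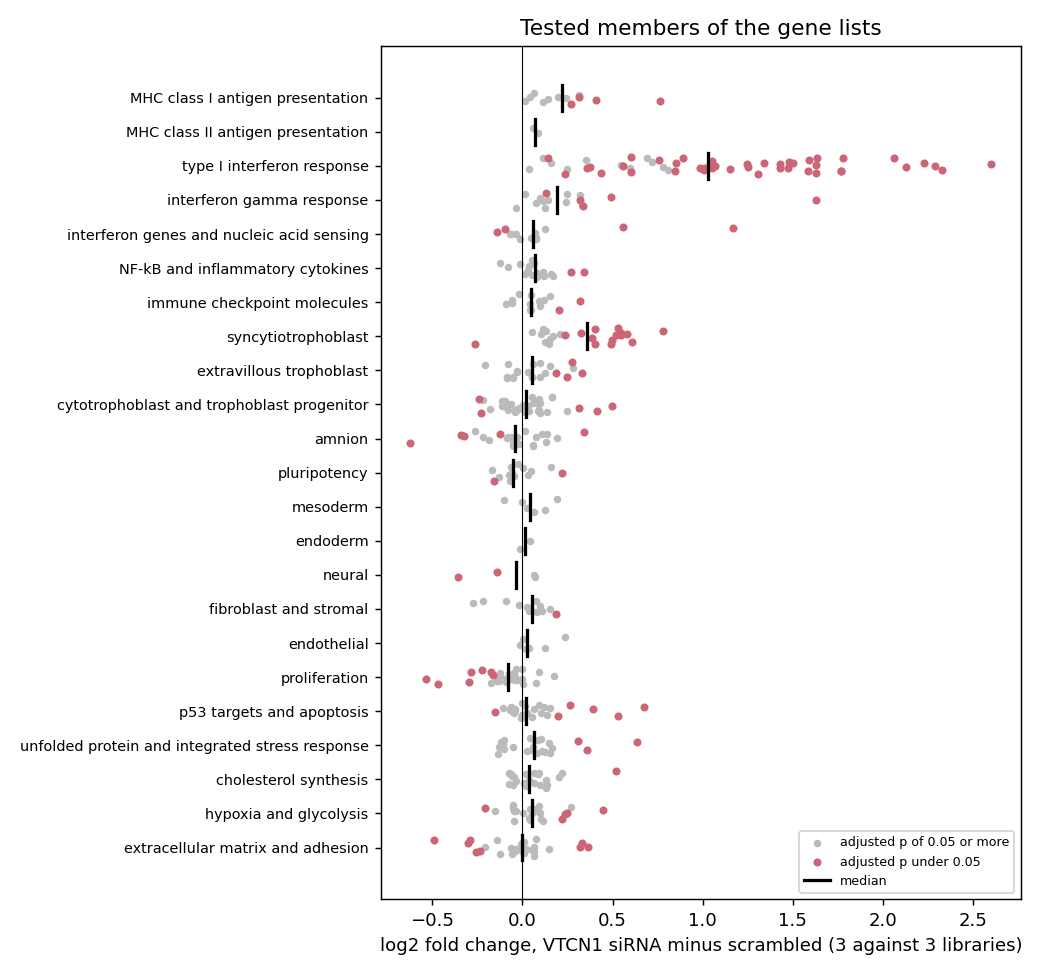
Log2 fold change, knockdown minus control, of each tested member of 23 gene lists fixed before the data were examined; red points had an adjusted p under 0.05 over all genes and black bars mark list medians. The type I interferon list has a median of 1.03 and the syncytiotrophoblast list of 0.36, and the other medians lie between -0.08 and 0.22.

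Tested markers of pluripotent cells and other lineages showed few changes, but many listed markers could not be tested. Below the filter were 13 of 19 mesoderm, 12 of 15 endoderm, 13 of 17 neural, 12 of 15 hematopoietic and 9 of 25 pluripotency genes. Of 14 tested pluripotency genes, 1 rose and 1 fell, and 1 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.234). These were ZFP42, with a log2 fold change of 0.22, and CUZD1, with -0.16, and neither passed with passage as a block. None of 6 mesoderm, 2 endoderm or 6 endothelial genes passed, also when adjusted over the list alone (camera, adjusted p = 0.381, 0.827 and 0.205). The endothelial genes CDH5 and KDR had log2 fold changes of 0.24 and 0.13, the mesoderm gene TWIST1 had -0.10, and the endoderm genes PRDM1 and CXCR4 had 0.04 and -0.01. Of 4 tested neural genes, STMN2 and MAP2 fell by 0.36 and 0.14, also when adjusted over the list alone (camera, adjusted p = 0.196; directional fry, 0.00601, which did not pass with the block), and STMN2 passed with passage as a block. Of 13 stromal genes, the growth factor receptor gene PDGFRB rose by 0.19, and 1 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.381). PDGFRB did not pass with passage as a block (adjusted p = 0.322). The hematopoietic list had 1 tested gene, CSF1R, with a log2 fold change of 0.16 that did not pass (adjusted p = 0.353).

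On the proliferation list, 7 of 30 tested members fell, none rose and 23 did not pass, and 10 fell when adjusted over the list alone (camera, adjusted p = 4.16e-05; adjusted p = 0.620 with an estimated correlation). The replication helicase subunits MCM4 and MCM6 fell by 0.47 ± 0.04 (SE) and 0.30 ± 0.04 on the log2 scale, the mitotic kinase AURKA by 0.53 ± 0.05 and CDK1 by 0.29 ± 0.04. With passage as a block 2 members fell, MCM4 and AURKA, and in passages 53 and 54 alone 5 fell and 3 rose and the list's adjusted p was 0.115. The list's median difference was -0.21 in passage 52, -0.0038 in passage 53 and -0.13 in passage 54. Of 26 tested p53 targets and apoptosis genes, 5 rose and 1 fell, also when adjusted over the list alone (camera, adjusted p = 0.0636, and 0.0411 with passage as a block; 0.703 and 0.764 with an estimated correlation). In passages 53 and 54 alone 9 rose and 1 fell and the list's adjusted p was 0.00511, and it was 0.0193 without a filter and 0.0120 without either passage 52 library. The block left 4 that rose and none that fell. ZMAT3, an RNA-binding p53 target, rose by 0.67 ± 0.06, the stress cytokine GDF15 by 0.53 ± 0.06 and the cell cycle inhibitor CDKN1A by 0.39 ± 0.05.

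Metabolic, stress and matrix lists did not pass by camera in the main fit. Of 23 tested genes each, 3 rose on the unfolded protein and integrated stress response list, 1 rose on the cholesterol list, and 4 rose and 1 fell on the hypoxia and glycolysis list, with the same numbers when adjusted over each list alone. Their camera adjusted p values were 0.0833, 0.234 and 0.0636, and 0.753, 0.787 and 0.703 with an estimated correlation. Without a filter the unfolded protein list (0.0376) and the hypoxia list (0.0112) passed, and by quantile normalization the hypoxia list (0.0411). In passages 53 and 54 alone the camera adjusted p values were 3.05e-05, 7.08e-06 and 0.00107, all toward higher values in knockdown libraries. That fit had no passage block and was run with the preset correlation only, so these values may be too small. It also left out passage 52, where the list medians were -0.22, -0.25 and -0.19. With passage as a block 1 gene rose on each of these 3 lists, namely PSAT1, SC5D and VEGFA. PSAT1, an enzyme of serine synthesis, rose by 0.64 ± 0.07 (SE) on the log2 scale, the sterol enzyme SC5D by 0.52 ± 0.05 and VEGFA by 0.45 ± 0.06. Of 28 tested matrix and adhesion genes, 3 rose and 5 fell, also when adjusted over the list alone (camera, adjusted p = 0.384). THBS1, a matrix glycoprotein, fell by 0.49 ± 0.04 and COL4A1 by 0.29 ± 0.04, whereas the protease inhibitor TIMP2 rose by 0.37 ± 0.05, and with passage as a block THBS1 and TIMP2 passed.

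Apart from VTCN1, the largest decreases without overlap between the groups were those of CUTA and BCAT1. BCAT1, an enzyme of branched-chain amino acid breakdown on chromosome 12 at 24810022 to 24949459, fell by 1.06 ± 0.04 (SE) on the log2 scale, from a control value of 12.16 ± 0.03 (SD, n = 3, adjusted p = 1.89e-05). LAGE3 fell by 0.85 ± 0.04 and ARL6IP6 by 0.70 ± 0.04. The amino acid transporter SLC7A5 and the G1 cyclin CCND1 both fell by 0.68 ± 0.04, and the cytokinesis protein ANLN and the mitochondrial enzyme IDH2 both by 0.65 ± 0.04. CUTA had a log2 fold change of -1.60 ± 0.15 but lies within the MHC region at 33416442 to 33418317, where most genes were listed at 0, and its value is uncertain. All genes named in this paragraph also passed with passage as a block. With the block the SE was 0.072 for BCAT1, 0.076 for SLC7A5 and 0.065 for CCND1, larger than without it, but for CUTA it was smaller, at 0.081.

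The 3 passages did not show the same direction for every gene. Of 186 genes that differed by at least 0.5 in the same direction in passages 53 and 54, 136 differed the same way in passage 52 and 50 the opposite way. In 7 of them the passage 52 difference was within 0.3 times the mean of the other 2 passages. Over all tested genes, 3921, or 29.1%, had the same direction in all 3 passages, where independent directions would give 25%. The 3 knockdown libraries did not overlap the 3 control libraries for 3361 genes, or 24.9%. When control and knockdown were exchanged within passage 52, 53 or 54 the number was 3822, 2655 or 1442, so the real grouping did not give the most.

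**Figure D3:**
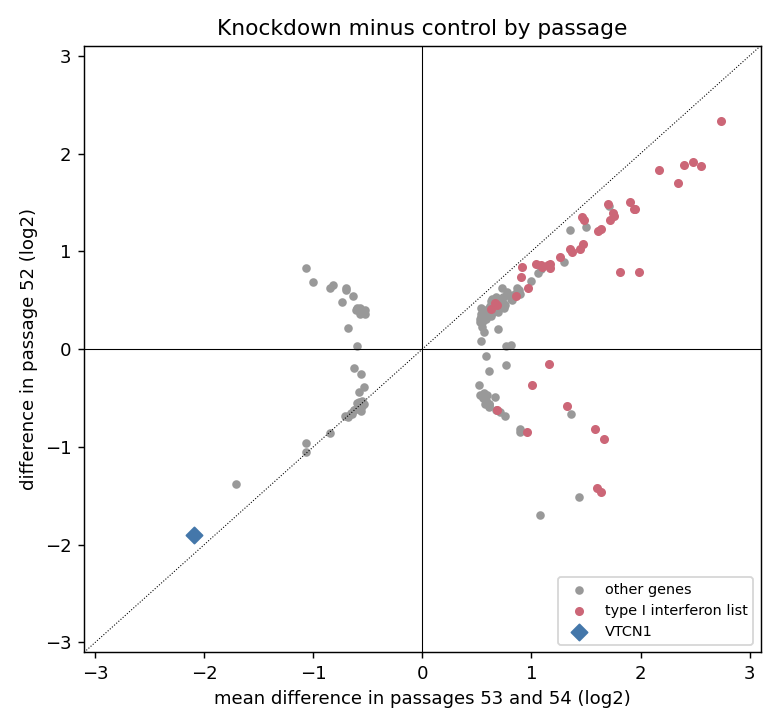
Knockdown minus control difference (log2) in passage 52 against the mean of the differences in passages 53 and 54, for the 186 genes that differed by at least 0.5 in the same direction in passages 53 and 54; the dotted line marks equal values. VTCN1 (blue) and 37 of 46 type I interferon genes (red) have the same sign on both axes, and 50 of all 186 genes have opposite signs.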

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

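The passage block, passages 53 and 54 alone, quantile normalization, the filter at 8, the robust prior, the fit without trend, mixed fry and the random directions were chosen after seeing the data. VTCN1 kept its direction and call under all alternatives run, at -2.10 to -1.98 when a library was left out. With the passage block 356 genes changed (214 higher, 142 lower), against 1237 (627 and 610) without it, and in passages 53 and 54 alone 2622 changed (1549 and 1073); the cause was not tested. Leaving out each library gave 650 to 967 changed genes, 333 to 600 higher and 317 to 436 lower, with fewer samples in each fit: 650 and 679 without the control or knockdown library of passage 54, 809 and 754 without those of passage 53, and 367 and 371 lower without those of passage 52. An adjusted p under 0.01 left 588 (307 and 281) and a log2 size of at least 1 left 37 (33 and 4), by construction. Centring, quantile normalization and the filters kept these counts within 1.5 times.

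Of 23 lists tested by camera, 7 were called. With estimated correlations 0 were called, without or with the block; at an unadjusted p under 0.05 type I interferon was called without the block (0.0334). By directional fry 4 were called: type I interferon and neural (both 0.00601), and interferon gamma and syncytiotrophoblast (both 0.0318). MHC class I (0.0509), NF-kB and checkpoint (both 0.0606) and proliferation (0.0926) lost their call. With the block directional fry called 0, and type I interferon had an unadjusted p of 0.0152. Mixed fry (either direction) called 17, the 7 of the main test included, and also matrix and adhesion (5.53e-07), amnion and pluripotency (both 9.41e-06) and 7 more, and with the block it called 3, amnion and matrix (both 0.0394) and type I interferon (0.0440). Without a filter 11 were called, with p53, unfolded protein, hypoxia and interferon genes added, and with the filter at 8 checkpoint lost its call. When a library was left out 6 to 12 were: 12 without either passage 52 library, 6 without either of passage 53, where checkpoint lost its call, and 8 without either of passage 54, where amnion gained one; the cause was not tested. The block with the preset correlation changed the call of the p53 list, which passed (0.0411; 0.764 with an estimated correlation, 0.610 by fry), and of no other list. Reversed lists were not called: matrix and adhesion in passages 53 and 54 (adjusted p = 0.655), and mesoderm and endoderm without a filter (0.791 and 0.646). Without a library, directions also reversed for lists and genes not called: endoderm (adjusted p 0.652 to 0.912), stromal (0.207 to 0.935), cholesterol synthesis (0.0066 to 0.906, reversed at 0.898), HLA-C (-0.038 to 0.094) and CXCR4 (-0.031 to 0.0049). HLA-C was -0.068 in passages 53 and 54. Named genes lost their call with the block (26), without a filter (8), with equal totals (4), in passages 53 and 54 (4), without trend (1) and without a library: 4 for either of passage 52, 12 for either of 53, and 15 and 14 for control and knockdown of 54.

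The 10 splits of the 6 libraries are too few for a share under 0.05. As many genes as in the real split (1237) were called in 2, the real one included; the highest other (1363) exchanges the labels of the passage 52 pair. With the passage block that split called 14 genes and the real one 356. With random directions and sizes kept, 20 draws called 447 to 617 genes, and 5 to 26 with the block, but genes were drawn independently and these ranges may be too narrow. Count tests, voom, CPM filter and pseudocount were not run on log2 values, and passage replaced the titles' replicate numbers, which the columns lack. Without counts, depth limits cannot be stated.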

Other observations

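All tests here except the one on chromosome 19 genes were chosen only after the result was seen, and so were the genes and families named. Cytosolic ribosomal protein genes had a median log2 fold change of -0.07 over 80 genes, of which 5 fell, 1 with passage as a block, and none rose. Their median difference was -0.15, -0.02 and -0.10 in passages 52, 53 and 54, and no test of the family was run. Over all 13488 tested genes, 610 fell, and 142 with the block. Mitochondrially encoded transcripts, 15 in number, split by passage, with median differences of -0.25, 0.32 and 0.25 in passages 52, 53 and 54, and 2 rose, 1 with the block. HBB, a globin gene, had a value of 12.40 in the control library of passage 52 and 5.44 to 5.70 in the other 5 libraries, while HBA2 was at 1.27 to 1.38 in all 6.

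The first pattern is the set of passage 52 differences that ran against passages 53 and 54, as for the interferon-induced genes SAMHD1, at 10.01 in control and 8.55 in knockdown of passage 52 against 8.60 and 10.18 in passage 53, and DDX60. An exchange of the passage 52 labels as a whole is argued against by VTCN1, which was lower in the knockdown library of that passage by -1.902. A response weaker for all interferon genes together is argued against because 8 of 46 list members that were higher in both other passages were lower by at least 0.3 in passage 52, 17.39% (95% exact interval 7.82 to 31.4). The interval treats the genes as independent, though they come from a single pair of libraries, and it measures no spread between replicates. An adjustment of level and spread of most genes within each passage before deposit could not be decided by its test, which ran on genes chosen for the pattern. Over all tested genes, passage means had a median SD of 0.018, against 0.052 for the mean size of passage differences divided by 2. Deviations of paired libraries were negatively correlated (Pearson's r of -0.80, -0.71 and -0.62 in passages 52, 53 and 54). Differences in level between passages would move both libraries of a pair the same way. For most genes these values therefore argue against such differences in the deposited values. Libraries that varied independently of each other around equal passage levels would show no such negative correlation, so these values argue against that too. Removal of differences in level between passages before deposit would leave values of this kind. The values alone do not show that it was done. Among 785 genes with the opposite direction in passage 52 and a mean size of at least 0.2, the smallest size of the 3 differences was 0.6422 of the largest at the median, against 0.329 over all genes. The same choice gave a median of 0.272 in normal differences with each gene's spread and of 0.322 when passage 52 sizes were exchanged among genes of like mean value. It gave 0.581, with a range of 0.565 to 0.600 over 100 draws, when they were exchanged among genes of like size in passages 53 and 54. The highest draws of the first 2 kinds were 0.302 and 0.352, so the observed 0.6422 lay above every draw of each kind. The last kind of exchange alone went past the limit set for this test, so the test did not decide. HBB and C9orf64, with 6.73 in passage 52 and 7.79 to 8.22 in the others, were not levelled, and no record of such a step was in the sources used here. Biological differences between passages in the knockdown minus control difference stay open as untested.

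The second pattern concerns the MHC region of chromosome 6, where most protein-coding genes were listed at 0. Silence of the region in these cells is argued against because 17 of 20 broadly used genes there, such as RPS18 at 0, were below the filter. Loss of reads to alternate copies of the region in the reference may be proposed, but 0 of 8 broadly used genes of the leukocyte receptor region of chromosome 19, which also has alternate copies, were below the filter, with means of 8.55 to 15.2, which argues against such copies as a general cause. Loss specific to the chromosome 6 copies or to the annotation of this region stays open as untested. HLA-A, HLA-B and HLA-C values may therefore understate their transcripts, and their differences are uncertain. Class I genes outside the region, such as B2M, are not touched by this pattern.

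The third pattern is the rise of type I interferon genes, 42 of 54. Both groups received siRNA by lipofection, and double-stranded RNA can induce these genes, so a response of the cells to the VTCN1 siRNA reagent itself rather than to loss of VTCN1 is a candidate explanation. There was 1 knockdown group, so these cannot be told apart: no group with another reagent against VTCN1, and no untransfected group, was analysed here.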
